A study of Mus musculus with 2 samples.

How the data were processed

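The files hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, deposited as sparse matrices for 2 libraries made with a microwell single-cell kit. Per the labels, alveolar bone was minced, digested for 60 min with the kit's dissociation solution, filtered, and freed of red cells by lysis. Each group was a pool of 6 mice, and no source used here ties a library to the force or the control group. The aligner, the counting program and the gene annotation are not given in the sources used here. The submitters' processing notes name FastQC 0.11.9 and the genome builds GRCh38, a human build, and mm10, a mouse build, without a role for either. The features carry mouse gene identifiers with symbols, and symbols are used here as the files pair them. Of 57126 gene identifiers, 51884 occur in the GENCODE M21 mouse annotation when the version is ignored and only 35 in the same version, so no coordinates are given. The files hold 99819 features, of which 42693 carry no gene symbol. These were left out, and they held 0.602% of the UMIs of library 1 and 0.431% of those of library 2. Paralogs with nearly the same sequence, such as the haemoglobin, Bglap and MHC class I genes, may share reads, and their counts are uncertain. A few symbols of the lists below, Azu1, Ctgf, Cyr61 and Vpreb1, did not match a symbol in the files and were not analysed here.

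The matrices are unfiltered. Of 1769472 possible barcodes, 1636474 had a UMI in library 1 and 1672095 in library 2. A barcode was called a cell if its UMI total reached the larger of 500 and the inflection of the barcode rank curve, which lay at 816 and 1036 UMIs, if it had at least 200 genes, and if at most 20% of its UMIs were mitochondrial. In library 1 these steps left 9927, 9908 and 9850 barcodes in turn, and in library 2 they left 12555, 12391 and 12200. Doublets were scored with Scrublet at an expected rate of 5%. Its automatic threshold marked only 1 and 2 cells, under 0.5%, so the call had not worked, and by the rule fixed in advance the 5% of cells with the highest scores were removed, 492 and 610 cells. Doublets may therefore remain. The median mitochondrial share of the 9358 and 11590 cells left was 1.44% and 1.81%.

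Both libraries were clustered together, without batch correction. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen within the libraries. Genes of the functional lists that are not cell markers were left out of the variable genes, as were mitochondrial, ribosomal and sex-linked genes. Then 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 were used. Genes of the functional lists that are also markers could shape the clusters. The 28 marker lists, with 207 genes, and the 23 functional lists, with 264 genes, were fixed before the data were examined. A cluster took the name of its best marker list if at least 3 markers and at least 50% of the list were raised at least 3-fold over all other cells, and if no other list had more genes among its 10 leading genes. The markers were fixed beforehand, but the limits of this naming rule were set after the leading genes and raised markers of the clusters had been seen, and other limits were not tried. Of 27 clusters, 23 were named, which gave 20 named classes, and 4 stayed unnamed, of which 1 is not reported here and the others are called by their 3 leading genes. Each class name means only that the cells are like that type by these markers. The genes that define a class are definitions and not results. Besides the cases given in the text, Itgb3, Car2, Bglap3, Lef1, Ccl7, Ccl8, Il10, Fpr1, Il1b and Il6 are also among the 10 leading genes of a cluster of the class for which they are reported, and Il4 is among the 10 genes that define its class. Mature neutrophil-like cells comprised a cluster led by Asprv1, Il1b and Hcar2, with 1399 and 552 cells, and a cluster led by Retnlg, Mmp8 and Fpr1, with 727 and 701 cells.

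Cells are not replicates and there is 1 library per possible group, so no test was made and no p-value is given. UMIs were summed per class and library and given as CPM, the count scaled to the total of that class and library, with exact Poisson intervals, and shares of cells have exact Clopper-Pearson intervals, both at 95% and both for counting error only. A gene was measured if it had at least 20 UMIs in some class in each library, and a class was called highest only if it was so in both libraries. Only the 22 classes with at least 30 cells in both libraries were ranked. Levels under that of 0.5 UMIs were set to it before ratios of the highest to the next class were taken. This floor, the 2-fold limit and the margin for counting error below were not among the choices fixed beforehand. A gene is said to be within counting error if the lower of its log2 ratios over the libraries did not exceed 0 by 1.96 counting standard errors. That held for 12 of the 94 genes looked up, counting those without a shared highest class, and the other 82 passed. For shares of cells with a UMI, each cell was thinned to 500 UMIs, which left out no cell, and the share in mature B-like or osteoblast-like cells served as background. For a share of 0, the limit given is that of 3 cells, while the count of genes above the background class used the exact interval there. RNA outside cells was taken from barcodes with 1 to 100 UMIs. The same profile served as the free RNA in the subtraction below, and where the UMIs of these barcodes came from was not tested.

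The genes named in the text follow a rule fixed before the data were examined. They are 14 genes that were always to be given, up to 4 genes of each functional list with the largest ratio of highest to next class, the 10 genes that define each class, the 10 genes most raised outside cells, and, in the closing section, the 5 genes with the highest and the 5 with the lowest ratio of library 2 to library 1 in each of the 3 largest classes. Snx10, Tcirg1 and Ctsk in osteoclast-like cells fall outside this rule and were chosen after their values were seen, as were all values given for osteoclast-like cells, which were too few for the ranking. In the closing section the median log2 ratio of each functional list between the libraries was set against 10000 random lists of the same size matched on mean level, as a description of these 2 libraries only.

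The alternatives fixed in advance were other UMI minimums, a mitochondrial limit of 10%, no removal of doublets, clustering resolutions of 0.5 and 2.0, 1000 variable genes, functional lists left in, clustering of each library on its own, the mean of the shares per cell, subtraction of free RNA, thinning to 1000 UMIs, barcodes with 10 to 100 UMIs, and scaling by the median of ratios. A minimum of 20 cells per class was added after the data were seen. The steps were checked on simulated counts of 12447 genes. For the ranking, every class was drawn at its real UMI total from a single profile pooled over all classes and both libraries. Apart from the raised genes, the classes did not differ there, unlike the real ones. Of 67 genes raised 3-fold in a random class, 85.1% were placed in the right class in both libraries and 28.4% also passed the 2-fold limit. Of 67 genes raised 5-fold, 98.5% were placed and 88.1% passed, and of 66 genes raised 10-fold, 100% were placed and 98.5% passed. Among unchanged genes, 10.6% had the same highest class by chance and 0.0163% passed the 2-fold limit. In a simulation of the list medians, both libraries were drawn from the pooled levels of each class. A shift of -2 (log2) put into library 2 was found in 19 of 19 classes with a middle value of -2.02. Of 392 combinations of unshifted lists and classes, 26 (6.63%) left the random range. Work was done in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and Matplotlib 3.10.9.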

Results

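Single-cell RNA libraries were analysed from mouse alveolar bone, the part of the jaw that holds the tooth roots, taken in a study of orthodontic tooth movement. Per the labels, 12 mice were divided between a group whose first molar was pulled by a coil spring at 25 g and a control group that carried the spring without force. Bone within 1 mm of the socket was taken on day 7, and the tissue of 6 mice was pooled for each group. The labels of the 2 libraries do not say which group either came from, so they are called library 1 and library 2, and force was not compared with control. The question addressed here is which cells of this tissue carry the genes of bone resorption, bone formation and inflammation, as far as both libraries place them alike. Library 1 held 77572847 UMIs of named genes and library 2 held 116775367, of which 64.5% and 67.0% lay in called cells. Library 1 gave 9358 cells with a median of 3272.5 UMIs and 1314.5 genes, and library 2 gave 11590 cells with 4468 UMIs and 1535 genes. Each library is a single pool without replicates, so intervals are 95% limits for counting error only, and no test was made.

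**Figure D1:**
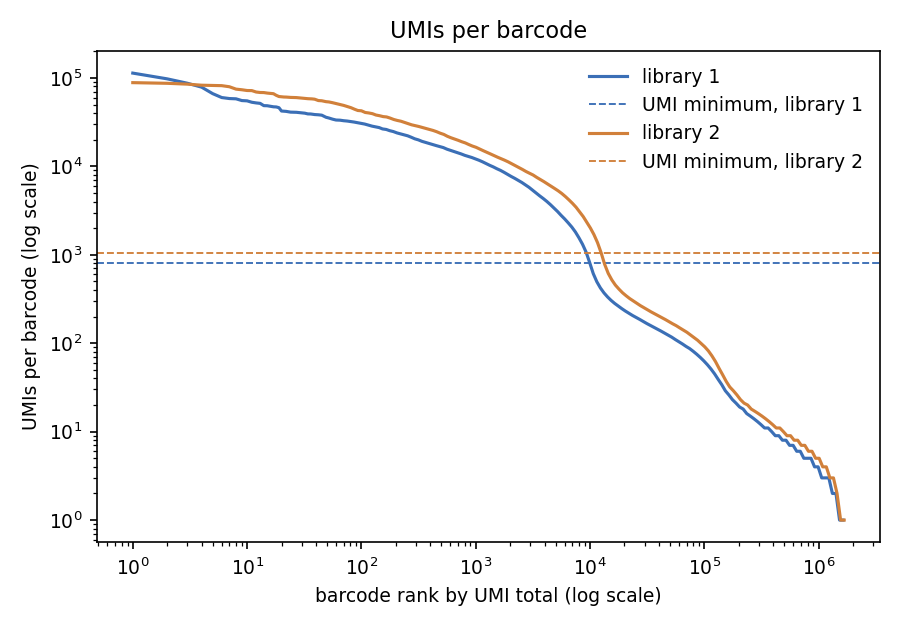
UMIs per barcode against the rank of the barcode, on log axes, for library 1 and library 2. The lines at 816 UMIs in library 1 and 1036 UMIs in library 2 mark the minimum for a called cell.

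Cells of the neutrophil lineage and cells of the stromal and bone-forming lineage were the most common groups in both libraries. Neutrophil-like cells made up 36.8% of library 1 (exact binomial interval 35.9 to 37.8) and 22.5% of library 2 (21.8 to 23.3). The stromal and bone-forming cells made up 25.5% (24.6 to 26.4) and 29.6% (28.8 to 30.4). B-lineage cells followed with 11.4% and 12.6%, and monocyte-like and macrophage-like cells together held 6.40% and 6.48%. Stem, progenitor and granulocyte-monocyte progenitor-like cells held 4.22% and 7.14%. Erythroid-like cells, which the red-cell lysis step would lower, held 2.12% and 7.53%. Among the smaller groups, endothelial-like cells held 3.23% and 5.09%, megakaryocyte-like cells 3.53% and 3.19%, and T-cell-like cells 3.10% and 1.82%. NK-like cells held 1.61% and 0.828%, plasmacytoid dendritic-like cells 0.801% and 1.959%, Schwann-like cells 0.470% and 0.544%, and basophil- or mast-like cells 0.353% and 0.526%. Osteoclast-like cells, the bone-resorbing cells, were rare, with 45 cells (0.481%) in library 1 and 25 cells (0.216%) in library 2. Tissue digestion and the UMI minimum can both set these shares, and the median depth ran from 1399.5 UMIs in megakaryocyte-like cells to 15436 in granulocyte-monocyte progenitor-like cells of library 1.

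**Figure D2:**
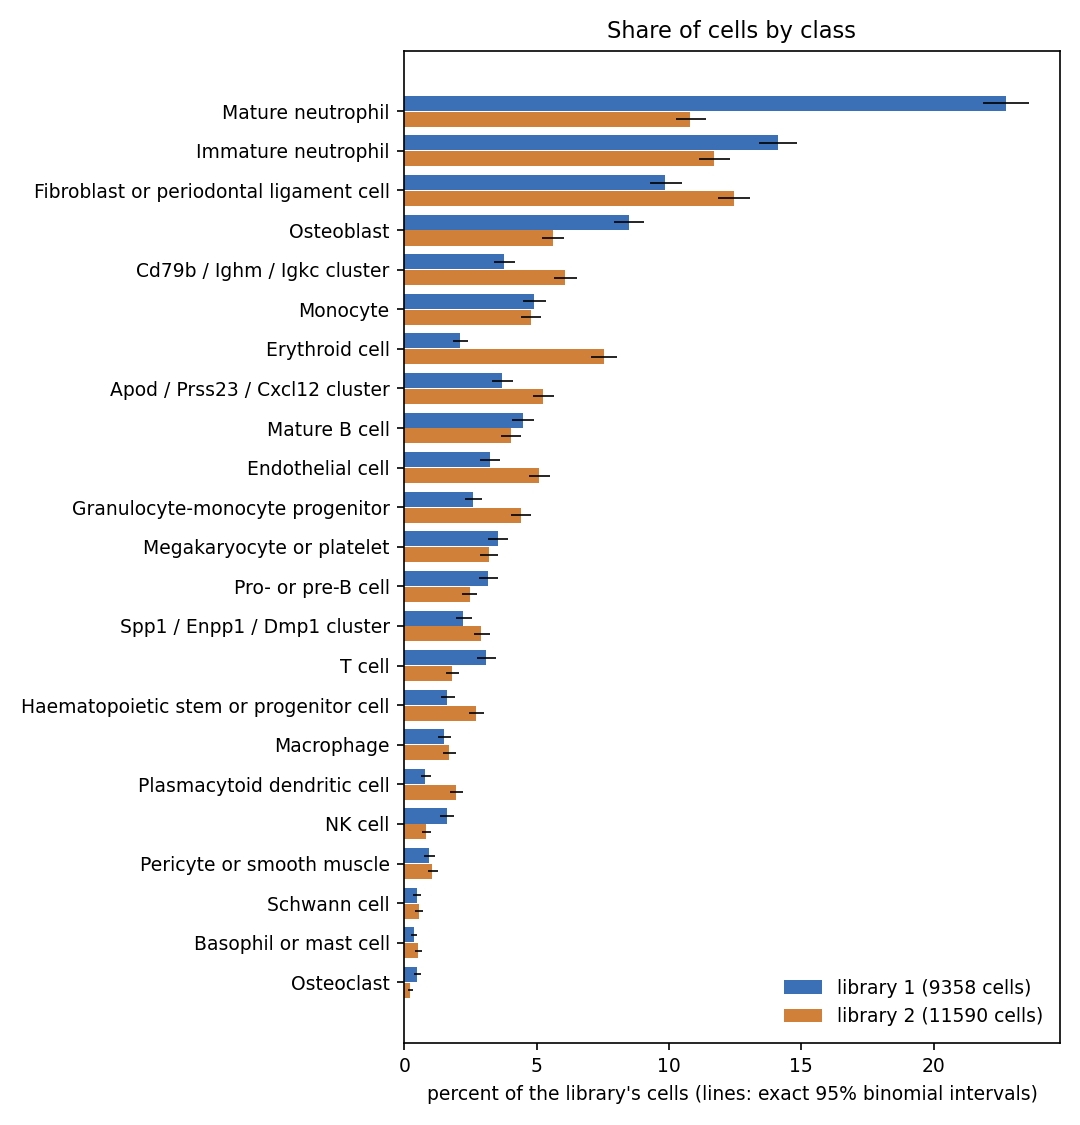
Percent of the called cells of each library in each ranked class and in osteoclast-like cells, with lines for the exact 95% binomial interval. Mature neutrophil-like cells held 22.7% of library 1 and 10.8% of library 2, and fibroblast- or periodontal ligament-like cells held 9.86% and 12.5%.

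Within the stromal and bone-forming lineage, several groups of cells could be told apart. Fibroblast- or periodontal ligament-like cells held 9.86% and 12.5% of cells and osteoblast-like cells held 8.48% and 5.62%. Pericyte- or smooth muscle-like cells held 0.940% and 1.06%. A cluster led by Apod, Prss23 and Cxcl12 held 3.70% and 5.25%, and the genes most raised in it included Adipoq, a gene of fat and marrow stroma. The pericyte list fitted it best, with 4 of 8 markers raised, but its leading genes belonged to other lists, so it stayed unnamed. A cluster led by Spp1, Enpp1 and Dmp1 held 2.23% and 2.92%. Dmp1 is known from osteocytes, the cells enclosed in bone, but only 2 of the 6 osteocyte markers were raised there, so this cluster also stayed unnamed. Osteoclast-like cells were left out of the ranking of classes because of their few cells in library 2. No cluster met the marker lists of dendritic cells, plasma cells, CXCL12-rich marrow stroma, osteocytes, chondrocytes, epithelium, skeletal muscle or odontoblasts. This does not show that such cells were absent, since they may lie within other classes. Adipoq and Cxcl12, both high in the Apod cluster, belong to the list of CXCL12-rich marrow stroma. Cd209a, of the dendritic cell list, is among the genes that define monocyte-like cells.

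Tnfsf11 and Tnfrsf11b, which act against each other in osteoclast formation, were both highest in stromal clusters among the ranked classes. Whether these clusters differ is not settled, because the lead of the Apod cluster over the Spp1 cluster for Tnfsf11 was small in library 2. Tnfsf11, which encodes the osteoclast-inducing ligand RANKL, was highest in the Apod cluster, at 281 CPM (exact Poisson interval 256 to 307) in library 1 and 169 (154 to 184) in library 2. The Spp1 cluster came next with 178 (154 to 204) and 153 (136 to 172), so the gap between these groups in library 2 was within counting error. Fibroblast- or ligament-like cells held 125 and 87.5 CPM of Tnfsf11, and osteoblast-like cells 19.3 and 16.4. Tnfrsf11b, which encodes the decoy receptor osteoprotegerin, was highest among the ranked classes in the Spp1 cluster, at 130 (110 to 152) and 179 (160 to 199), ahead of the fibroblast- or ligament-like cells with 81.1 and 85.3. The receptor gene Tnfrsf11a, which encodes RANK, was highest among ranked classes in macrophage-like cells, at 73.6 (59.2 to 90.5) and 54.0 (42.2 to 67.9), and osteoclast-like cells held 114 and 176. Csf1r, the receptor gene of the growth factor CSF1, stood at 298 (268 to 330) and 409 (376 to 445) in macrophage-like cells, above the monocyte-like cells at 234 and 303, and at 881 and 1186 in osteoclast-like cells.

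Of the 14 genes in the list of osteoclast-controlling ligands and receptors, all were measured, 10 had the same highest class in both libraries and 3 of these lay at least 2-fold above every other class in both. These 3 were Tnfrsf11a, Ephb4 and Traf6. Ephb4, at 49.6 and 49.2 CPM in endothelial-like cells, was within counting error, since the next class in library 1, Schwann-like cells, rested on 3 UMIs. Tnfrsf11a lay below the unranked osteoclast-like cells. The 10 were divided over stromal, macrophage-like, neutrophil-like, endothelial-like and B-lineage classes. Traf6, a signal adaptor used by RANK, was highest in an unnamed B-lineage cluster led by Cd79b, Ighm and Igkc, at 227 and 197 CPM. Csf1 had no shared highest class. It stood highest in basophil- or mast-like cells in library 1, at 516 (414 to 635), and in the Apod cluster in library 2, at 270 (252 to 289). Il34, another ligand of the CSF1 receptor, was highest in pericyte- or smooth muscle-like cells at 76.1 and 79.1, but its gap to Schwann-like cells in library 1 rested on 7 UMIs there and was within counting error.

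Some genes of the resorption machinery were high in osteoclast-like cells, and others were higher in other classes. Snx10, needed for the acid secretion of osteoclasts, reached 1135 and 1548 CPM in osteoclast-like cells, and Tcirg1, a subunit of the proton pump, reached 757 and 846. Both were chosen after their values were seen. Acp5 at 12834 and 28639 and Ctsk at 16383 and 32550 are markers of the class, and Mmp9, a collagen-degrading protease, at 9806 (9490 to 10131) and 12729 (12434 to 13029), is one of its leading genes, so these restate its definition. Among the classes with enough cells for the ranking, 12 of the 13 genes had the same highest class, 4 by at least 2-fold, and 6 of the 13 are also class markers. Acp5 was then highest in macrophage-like cells at 859 and 297, Mmp9 in mature neutrophil-like cells at 773 and 1469, Car2 in erythroid-like cells at 3403 and 3799, and Itgb3 in megakaryocyte-like cells at 1701 and 1812. Entry of the osteoclast-like cells into the ranking, an alternative added after the values were seen, moved Acp5, Mmp9, Csf1r and Tnfrsf11a to that class, while Car2 and Itgb3 kept theirs.

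**Figure D3:**
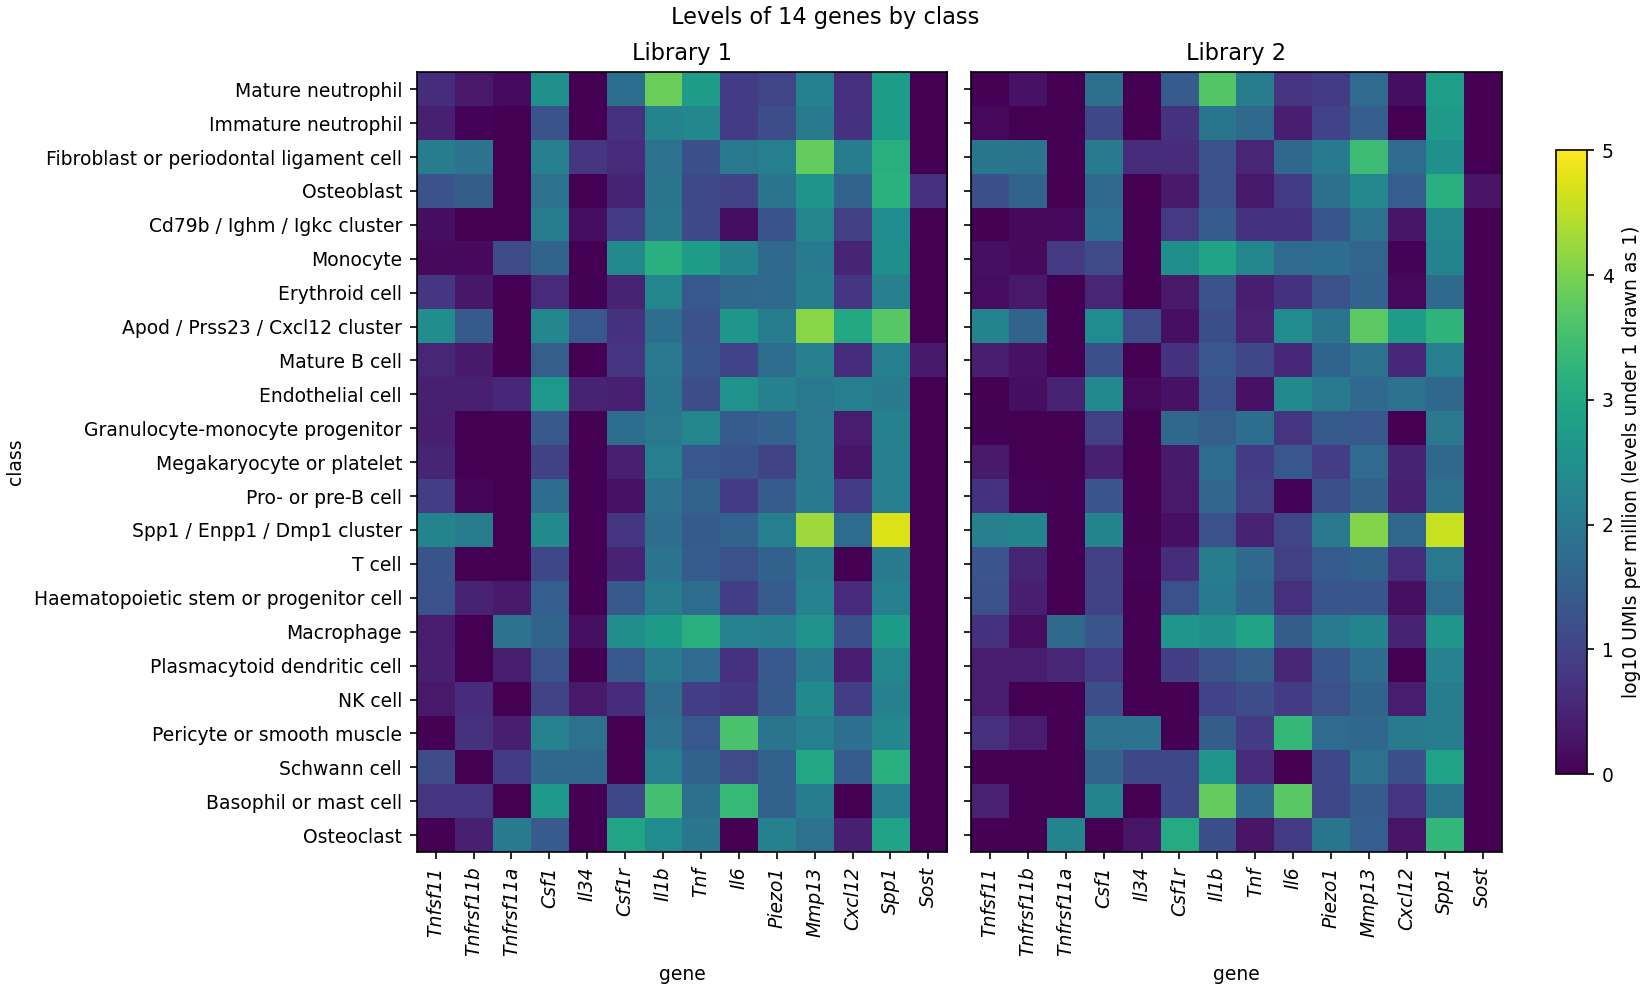
Levels of named genes by class in CPM of the class, on a log scale, for library 1 and library 2. Tnfsf11 stood at 281 and 169 in the Apod cluster, and Mmp13 at 18771 and 11850 in the Spp1 cluster.

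The Spp1 cluster carried the highest levels of several genes of mineral control and matrix turnover. Spp1, which encodes the bone matrix protein osteopontin, stood at 54883 (54454 to 55314) and 37766 (37489 to 38044) CPM, and Enpp1, which makes the mineralisation inhibitor pyrophosphate, at 425 and 492. Ank, which controls extracellular pyrophosphate, stood at 927 (872 to 984) and 916 (873 to 960), ratios of 7.29 and 7.32 to the next class. The collagenase gene Mmp13 reached 18771 (18521 to 19024) and 11850 (11695 to 12006) there, against 12910 and 5586 in the Apod cluster. Timp1, an inhibitor of matrix proteases, reached 4177 and 2532. All of these are among the leading genes of the cluster, so their place restates what defines it. In the list of bone matrix and mineralisation genes, 11 of 12 were measured, 9 had the same highest class and 4 did so by at least 2-fold. Osteoblast-like cells were highest for 5 of the 9. Among them, Bglap3 stood at 1294 and 2133, but it shares sequence with Bglap and Bglap2, so its counts are uncertain. Among 12 measured matrix proteases and inhibitors, 8 had the same highest class and 4 did so by at least 2-fold. Adamts1 and Adamts4, proteoglycan-cleaving enzymes, were highest in pericyte- or smooth muscle-like cells, Adamts1 at 3714 and 3759 and Adamts4 at 672 and 584. Mmp12, a macrophage elastase, was highest in macrophage-like cells at 34.4 and 36.0.

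Wnt and bone morphogenetic protein (BMP) genes were divided among many classes, most often stromal ones. Of 16 measured Wnt genes, 15 had the same highest class and 3 did so by at least 2-fold. Sfrp4, a secreted Wnt antagonist, was highest in the Spp1 cluster at 1530 (1459 to 1603) and 616 (582 to 653), where it is a leading gene, and Rspo3, which strengthens Wnt signalling, in the Apod cluster at 15.8 and 11.4. Lef1, a transcription factor of the pathway, was highest in pro- or pre-B-like cells at 320 and 313. Dkk2 was highest in endothelial-like cells at 38.7 and 18.7, a place within counting error. Sost, which encodes the osteocyte inhibitor sclerostin, was too rare to rank, with 36 and 10 UMIs in osteoblast-like cells. Among 16 genes of TGF-beta and BMP signalling, 10 had the same highest class and 2 did so by at least 2-fold. Bmp2, a bone-inducing ligand, was highest in the Spp1 cluster at 717 (669 to 768) and 566 (532 to 600). Bmp6 and the BMP antagonist gene Nog were highest in the Apod cluster, Bmp6 at 34.0 and 40.3 and Nog at 121 and 98.1. Bmpr2, a BMP receptor gene, was highest in endothelial-like cells at 399 and 511.

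Endothelial-like cells were the highest class for 6 of the 11 mechanosensing genes that had the same highest class in both libraries, out of 15 measured. The stretch-activated channel gene Piezo2 stood at 76.4 (65.3 to 88.9) and 53.5 (46.5 to 61.2) there, ratios of 5.82 and 6.59 to the next class. Wwtr1, which encodes the mechanically regulated coactivator TAZ, stood at 690 and 849. Piezo1 was also highest in endothelial-like cells, at 158 (142 to 176) and 122 (112 to 134), but macrophage-like cells at 149 in library 1 and fibroblast- or ligament-like cells at 112 in library 2 lay within counting error of it. Ccn2, a target of the coactivators YAP and TAZ, was highest in the Spp1 cluster at 1242 and 2070, and Vcl, which encodes the adhesion protein vinculin, in megakaryocyte-like cells at 758 and 765. Only 2 mechanosensing genes, Piezo2 and Wwtr1, lay at least 2-fold above every other class in both libraries. Of 13 measured genes of hypoxia and angiogenesis, 8 had the same highest class and 2 did so by at least 2-fold. These were Tek, an angiopoietin receptor gene, in endothelial-like cells at 191 and 219, and Ndrg1, a stress-response gene also active in myelinating cells, in Schwann-like cells at 2042 and 1596.

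Endothelial-like cells also carried several genes that capture and mobilise neutrophils. Of 10 genes of neutrophil retention and release, 9 had the same highest class and 6 did so by at least 2-fold, and endothelial-like cells were highest for 5. The adhesion genes Selp and Sele stood at 4942 (4850 to 5036) and 6286 (6208 to 6364) and at 938 and 1097, and both are leading genes of the class. Csf3, which encodes the growth factor G-CSF, stood at 598 (566 to 631) and 361 (343 to 381), and its receptor gene Csf3r at 1012 and 860 in mature neutrophil-like cells, of which it is a marker. In the list of the haematopoietic niche, 7 of 9 genes were measured and all 7 had the same highest class, 2 by at least 2-fold. Cxcl12, which retains blood stem cells in the marrow, stood at 1026 (978 to 1075) and 549 (523 to 576) in the Apod cluster, whose name it shares. Jag1, a Notch ligand gene, was highest in pericyte- or smooth muscle-like cells at 417 and 314. Flt3l was highest in megakaryocyte-like cells at 46.4 and 47.3, within counting error of the next class.

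Macrophage-like cells were the main site of several chemokines. Of 18 measured chemokine genes, 14 had the same highest class and 10 did so by at least 2-fold, and 6 of the 14 were highest in macrophage-like cells. Ccl7, a monocyte attractant, stood there at 4001 (3890 to 4114) and 2209 (2130 to 2290), ratios of 33.6 and 29.1 to the next class. Ccl8 stood at 1566 and 185, and Ccl12, one of the genes that define the class, at 985 and 202. Cxcl5, a neutrophil attractant, was highest in megakaryocyte-like cells at 410 (378 to 444) and 233 (213 to 254).

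Among 17 measured inflammatory cytokines and receptors, 12 had the same highest class and 6 did so by at least 2-fold. Tnf was highest in macrophage-like cells at 1364 (1300 to 1431) and 832 (784 to 882), and the anti-inflammatory Il10 at 1111 (1053 to 1171) and 1021 (968 to 1077). The type 2 cytokine genes Il4 and Il13 were highest in basophil- or mast-like cells, Il4 at 217 and 394 and Il13 at 99.6 (58.0 to 160) and 281 (228 to 343), with only 33 and 61 cells in that class. Ifng was highest in NK-like cells at 304 and 277. Il1b and Il6, cytokines that promote bone resorption, had no shared highest class. Il1b stood at 7257 (7183 to 7333) and 4660 (4592 to 4728) in mature neutrophil-like cells and at 3165 (2903 to 3443) and 6642 (6373 to 6920) in basophil- or mast-like cells. Il6 stood at 3643 (3454 to 3840) and 2156 (2016 to 2304) in pericyte- or smooth muscle-like cells and at 2209 (1992 to 2444) and 5225 (4986 to 5472) in basophil- or mast-like cells.

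Many genes of the neutrophil granules are also markers of the granulocyte classes, so their places restate the class names. Of 7 measured azurophil granule genes, 4 of them markers, 6 had the same highest class, and Mpo, Elane, Ctsg and Prtn3 were highest in granulocyte-monocyte progenitor-like cells, with Mpo at 6894 and 8610. These are the 4 markers, and the 2 other genes were highest in monocyte-like and in immature neutrophil-like cells. In library 2 the 63 Schwann-like cells held 2892 CPM of Mpo, 2823 of Elane and 3147 of Prtn3. All 8 measured specific granule genes, 5 of them markers, were highest in immature neutrophil-like cells, 5 by at least 2-fold. Orm1, which is not a marker but leads the class, stood at 160 and 133 there, and Camp, which encodes an antimicrobial peptide, at 44154 and 44955. Of 8 gelatinase granule genes, 6 had the same highest class, and 4 were highest in mature neutrophil-like cells by at least 2-fold, although the place of Mmp9, one of the 4, turned in 7 of 11 other ways of processing. Among these, Fpr1, a receptor gene for bacterial peptides, stood at 1503 and 777, and Adam8, a surface protease gene, at 1248 and 1504.

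The macrophage lists were not carried by macrophages alone. Of 9 measured genes of inflammatory macrophages, 8 had the same highest class, none by at least 2-fold, and 4 were highest in mature neutrophil-like cells, among them the co-stimulatory gene Cd80 at 201 and 147 and the lipopolysaccharide receptor gene Tlr4 at 124 and 94.5. Irf5 was highest in monocyte-like cells at 246 and 317, and Cd86 in macrophage-like cells at 398 and 292. Of 10 measured genes of alternative activation, 9 had the same highest class and 5 did so by at least 2-fold. The mannose receptor gene Mrc1 at 400 and 584, Trem2 at 170 and 149 and Cd163 at 33.5 and 80.2 were highest in macrophage-like cells, but all 3 are markers of that class.

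Interferon, antigen presentation, proliferation and stress genes gave less sharp rankings. Of 11 interferon response genes, 6 had the same highest class and 2 did so by at least 2-fold. Ifit2 was highest in macrophage-like cells at 1059 (1002 to 1119) and 126 (108 to 146). Mx1, Usp18 and Irf7 were highest in plasmacytoid dendritic-like cells, with Mx1 at 795 (709 to 889) and 110 (92.4 to 131), and Irf7 at 684 and 333, but macrophage-like cells stood above them for all 3 genes when each library was clustered on its own. Of 9 antigen presentation genes, 6 had the same highest class and 1 did so by at least 2-fold. That gene, Ciita, the regulator of MHC class II, stood at 60.1 and 55.4 in mature B-like cells, and the invariant chain gene Cd74 at 10193 and 11261. The place of Cd74 turned in 5 of 11 other ways of processing, and that of Ciita when a Cell Ranger rule kept only deep barcodes. H2-D1 was highest in NK-like cells at 4422 and 4176, within counting error of mature neutrophil-like cells. Among 10 proliferation genes, 8 had the same highest class, 5 of them in pro- or pre-B-like cells and 3 in erythroid-like cells. Top2a, a replication enzyme gene, stood at 1421 and 1665 in pro- or pre-B-like cells, and Mki67 at 2042 and 2364 in erythroid-like cells. Of the 11 genes of dissociation stress, which tissue digestion can raise, only Zfp36 had the same highest class, mature neutrophil-like cells at 2851 and 1821, within counting error in library 2. All 4 haemoglobin genes, which are erythroid markers, were highest in erythroid-like cells. Among the sex-linked genes 2 were measured, and Xist, which silences an X chromosome, was highest in stem- or progenitor-like cells at 1017 and 784.

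Over all genes, 13843 were measured in both libraries among the 22 ranked classes. The same class was highest in both libraries for 7670 of them (55.4%), where a random choice of class would give 4.55% and simulated genes without a class difference gave 10.6%. The classes came from clustering both libraries together, and the variable genes used for it were not left out of this count. Part of the agreement is thus built in, which neither of these figures allows for. For 1593 genes (11.5%) that class lay at least 2-fold above every other class in both libraries. Of 244 measured genes in the functional lists, 181 had the same highest class and 71 did so by at least 2-fold. Of the genes named above as highest in a class, Ndrg1, Rspo3, Bmp6, Orm1, Irf5 and Mki67 also lost that place when a Cell Ranger rule kept only deep barcodes, and Il13 did at a lower clustering resolution. The Spp1 cluster was ranked in only 6 of 11 other ways of processing and the Apod cluster in 9, so the places of their genes were tested in fewer.

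Most of the 14 genes that were always to be reported were seen in a larger share of the cells of their highest class than of a background class. The highest class came from these same counts, and the background was meant to lack the gene. These shares are therefore a description and no further support for the places. For Csf1, Sost, Il1b and Il6, which had no shared highest class, the highest class of library 1 was used. For Csf1 the background was osteoblast-like cells, which are a known source of it, so that comparison shows only a difference between these classes. After each cell was thinned to 500 UMIs, Tnfsf11 was seen in 14.5% (10.9 to 18.6) and 8.21% (6.16 to 10.7) of cells of the Apod cluster, against 0.239% and 0% of mature B-like cells, where the 0 of 466 cells allows up to 0.644%. Without thinning these shares were 50% and 36.1% in the Apod cluster, at median depths of 4278.5 and 4481 UMIs, and 0.716% and 0.644% in mature B-like cells, at 1869 and 1990 UMIs. Mmp13 was seen in 67.5% and 67.2% of the Spp1 cluster and in 6.92% and 4.29% of mature B-like cells. Il1b was seen in 71.1% and 60.7% of mature neutrophil-like cells and in 4.16% and 1.54% of osteoblast-like cells. Tnfrsf11a was seen in only 3 of 140 and 2 of 197 macrophage-like cells, against 0 of 794 and 0 of 651 osteoblast-like cells. In both libraries the lower limit of the thinned share lay above the upper limit of the background class for 12 of the 14 genes. The exceptions were Sost, seen in 1 osteoblast-like cell of each library, and Tnfrsf11a. Its lower limits in macrophage-like cells were 0.444% and 0.123%. The exact upper limits for 0 of 794 and 0 of 651 osteoblast-like cells, its background class, were 0.464% and 0.565%. At 1000 UMIs per cell the count was again 12, but Tnfrsf11a passed and Csf1 did not, and without thinning Tnfrsf11a was seen in 29.3% and 21.3% of macrophage-like cells.

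RNA outside called cells resembled that inside them for most lists of genes. Barcodes with 1 to 100 UMIs held 18.1% of the UMIs of library 1 and 12.8% of those of library 2, and whether these UMIs came from free RNA was not tested. Levels of the mature neutrophil markers outside were 0.889 and 0.898 times those in called cells, and those of the osteoblast markers 0.833 and 0.858 times. Genes of plasma cells, the antibody-secreting cells, stood 2.34 and 3.40 times as high outside, and mitochondrially encoded genes 1.34 and 1.44 times.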

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

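Of the tests in this part, none was chosen only after the result was seen, but the minimum of 3 genes for a list was added afterwards. The RNA of barcodes too poor to be called cells, which the ranking of classes does not use, held genes well above the level that a count of 0 allows, and 10 of them were named by the largest ratio of their level outside to inside called cells. Cmss1, which encodes a small-subunit ribosome factor, stood apart from the others by its abundance. It reached 6030 CPM outside cells in library 1 and 6068 in library 2, against 331 and 392 inside, ratios of 18.2 and 15.5. Ttr, a plasma transport protein gene of liver and choroid plexus, stood at 16.1 and 4.48 CPM outside cells, with 1 and 2 UMIs in all called cells. The other genes are pseudogenes or predicted genes. Rpl7-ps8 stood at 16.3 and 4.82 CPM outside, Gm18119 at 14.1 and 4.82, Gm4468 at 26.5 and 10.4, Gm11687 at 38.7 and 14.8, Gm14173 at 10.0 and 4.55, Gm5781 at 9.38 and 3.88, Gm48099 at 19.2 and 57.8, and Gm33838 at 20.3 and 9.16. Features without a gene symbol, also outside the ranking, held 0.602% of the UMIs of library 1 and 0.431% of those of library 2.

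Technical sources were weighed for Cmss1 only, and no biological explanation was tested, because the labels give no groups. Reads of ribosomal RNA counted to genes may be the source, since Lars2, a gene known to collect such reads, was 6.04 and 5.34 times as high outside, but Filip1l was at 0.996 and 1.09 times. Only these 2 genes of the list of 4 had counts enough, and their median ratio of 3.52 and 3.21 in the 2 libraries decides nothing with so few genes. Nuclear RNA set free from broken cells could also be the source. The median ratio of the 5 nuclear RNAs tested was 2.72 in library 1 and 2.11 in library 2, which lies between the bounds of 3 and 1.5 set before, with Malat1 at 1.47 and 1.49 and Kcnq1ot1 at 5.72 and 5.08. Both sources stay open for Cmss1 and cannot be told apart with these lists.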

How the results depend on the processing

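All alternatives were fixed in advance except the minimum of 20 cells per class, which was chosen after the data were seen. A log2 ratio was at first taken as reversed at any change of sign, which gave 74 changes in 25 genes. After these were seen, the rule was narrowed to genes past counting error, which left 47 changes in 18 genes, given below. The other 27 changes were in H2-D1, Zfp36, Tnfsf11, Sost, Il1b, Il6 and Piezo1, whose highest class lay within counting error of the next or was not shared by the libraries. Over 11 alternatives the list genes with the same highest class numbered 165 to 194, against 181, and those at least 2-fold above every other class 65 to 84, against 71. Of 957 log2 ratios of the highest to the next class, 544 moved by less than counting error, 366 moved further, and 47 turned, while the other 27 changes of sign are counted among those that moved less or further. A ratio was taken only where the class of the gene was ranked. For the Spp1 cluster, as with Tnfrsf11b, that held in only 6 of the 11 alternatives, and for the Apod cluster, as with Tnfsf11, in 9. In the other alternatives the places of their genes were not tested. Of 520 shares of the smaller classes, 320 stayed within their interval and 200 left it. No alternative tested a condition, and counting depth limits all rare genes and classes.

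With the minimum set by the first Cell Ranger rule, 3987 and 4410 cells were left, neutrophil-like cells held 25.4% and 20.2%, and stromal and bone-forming cells 37.2% and 32.4%. This rule keeps only deep barcodes, while mature neutrophil-like cells had median depths of 2040 and 2747 UMIs. Ratios then turned to -0.49 for Rspo3, -0.20 for Bmp6, -0.15 for Orm1, -0.091 for Irf5, -0.11 for Ndrg1, -0.25 for Usp18, -0.28 for Irf7, -0.054 for Mki67, -2.22 for Ciita and -1.39 for Cd74, and for these genes the cause was not tested. At 500 UMIs neutrophil-like cells held 33.9% and 18.9% and stromal cells 24.5% and 26.7%. With no doublets removed neutrophil-like cells held 35.4% and 21.3%. With 1000 variable genes they held 21.6% of library 2, and with the 10% mitochondrial limit stromal cells held 28.7% of library 2, by causes that were not tested.

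In 5 settings the osteoclast-like class had enough cells to enter the ranking and took the place of the class named in the report. Tnfrsf11a then gave -1.56 at 1000 UMIs, -1.49 at 500 UMIs, -1.51 with the mitochondrial limit, -1.56 with doublets kept and -1.71 with a minimum of 20 cells. In the same order Acp5 gave -6.56, -6.38, -6.53, -6.38 and -6.59, Mmp9 gave -3.24, -3.08, -3.38, -3.05 and -3.66, and Csf1r gave -1.41, -1.39, -1.45, -1.50 and -1.57. Tnfrsf11b gave -0.72 at 1000 UMIs and -0.66 with 20 cells, where another class entered the ranking and stood above. Cd74 fell below macrophage-like cells, to -0.60 at 500 UMIs, -0.53 with the mitochondrial limit and -0.65 with doublets kept.

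With each library clustered on its own, ratios were -1.51 for Mmp9, -0.49 for Mx1, -0.34 for Usp18 and -1.12 for Irf7, each below macrophage-like cells. At resolution 0.5 they were -1.68 for Mmp9, again below macrophage-like cells, -0.20 for Il13 and -0.42 for Mcm5, and the mean of the shares per cell gave -0.051 for Mcm5. In the main setting immature neutrophil-like cells came next for Mmp9, at 284 and 421 CPM, and macrophage-like cells lay lower. The osteoclast-like class was ranked neither at resolution 0.5 nor with each library clustered on its own, and its cells were not followed there. With free RNA subtracted the ratios were -0.11 for Irf5, -0.11 for Mx1, -0.65 for Irf7 and -0.85 for Cd74, each below macrophage-like cells, for which this estimate is void because a few cells hold their haemoglobin. The same step left the chemokine list below the random range in 12 classes in place of 19 and the haemoglobin list above it in 1 in place of 22, and it turned Hbb-bs in mature neutrophil-like cells to -7.09, as its construction requires, since haemoglobin sets the amount removed. Barcodes with 10 to 100 UMIs gave ratios of 22.0 and 17.1 for Cmss1. Apart from the cases given here, no other cause was tested.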

Other observations

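Values of the 2 libraries are set side by side in this part as descriptions of 2 pools, with no condition attached, and no biological explanation was tested because the labels tie neither to a group. The tests of the scaling and of haemoglobin from free RNA alone were chosen after the result was seen, as were the margins of 2 counting standard deviations, the use of other classes against the neutrophil weights and all choices of which patterns to describe.

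Most blood-cell classes of library 2 held less RNA of interferon-response genes than those of library 1, while several tissue classes differed little and erythroid-like cells did not follow. The list median was lower in library 2 than random lists of matched level in 15 of 19 classes, with a middle value of -1.90 (log2). It was -3.07 in macrophage-like, -3.02 in monocyte-like and -2.80 in plasmacytoid dendritic-like cells, -2.57 in mature B-like and -2.39 in pro- or pre-B-like cells. In the stromal classes it was -0.67 in fibroblast- or ligament-like cells, -0.49 in the Spp1 cluster, -0.15 in the Apod cluster and -0.09 in osteoblast-like cells, and it was -0.04 in endothelial-like cells. In erythroid-like cells it was -0.17, within the random range, but all genes there had a median of -0.79, and centred on it the list stood at 0.62. Chemokine lists lay below the random range in 19 of 22 classes, from -3.47 in erythroid-like cells, where the shift of all genes is part of the value, with basophil-like, NK-like and T-cell-like cells as the exceptions, but in only 12 with free RNA subtracted, and free RNA was not excluded as a cause there. Inflammatory cytokine genes lay below it in 14 of 19 classes and above it in 2.

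Other lists differed in how many classes left the random range and in which direction, and free RNA was not weighed as a source for them. The bone matrix list lay below the random range in 13 of 22 classes, with a middle value of -0.75 over the classes, but above it in the Spp1 cluster, at 0.21. Classes below it included endothelial-like cells at -0.72 and granulocyte-monocyte progenitor-like cells at -1.005. The Apod cluster at -0.10 and fibroblast- or ligament-like cells at 0.14 stayed within the random range. Azurophil granule genes lay above it in 13 of 20 classes, extracellular matrix proteases below in 13 of 19, specific granule genes below in 11 of 22 and above in 2, gelatinase granule genes below in 7 of 14 and above in 1, and resorption genes below in 8 of 19. Dissociation stress genes, which handling of the tissue can raise, lay below in 15 of 22 classes and above in 4. Osteoclast-controlling genes lay below in 8 of 18 classes, mechanosensing genes in 7 of 21, neutrophil retention genes in 7 of 19, niche genes in 6 of 11 and inflammatory macrophage genes in 4 of 13. Antigen presentation lay below in 8 of 22 and above in 3, proliferation below in 2 of 20 and above in 4, alternative activation below in 2 of 7 and above in 1, and hypoxia genes above in 1 of 22. Wnt genes in 13 classes and TGF-beta and BMP genes in 21 stayed within the random range. Proliferation genes stood above it in mature B-like cells at 1.34, in NK-like cells at 1.31 and in macrophage-like cells at 0.83. Haemoglobin also rose in these classes, from 0.0564%, 0.0388% and 1.70% of UMIs in library 1 to 0.939%, 1.86% and 3.30% in library 2. In library 2 the 5% of cells with most of it held 75.2%, 91.2% and 93.4%. Whether those cells also carry the proliferation genes was not tested.

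Among single genes of the largest classes, Mmp3, which encodes a matrix protease, had 160 UMIs in fibroblast- or ligament-like cells of library 1 and 4 in library 2, a log2 ratio of -6.14, and Pcp4 had 160 and 8 (-5.14). Dpep1 had 582 and 63 (-4.02), Dennd6b 80 and 5 (-4.82) and Gm33508 69 and 6 (-4.34), while Cartpt had 0 and 63 and Gm16189 1 and 70. In mature neutrophil-like cells Gbp5, an interferon-induced gene, had 282 and 13 UMIs (-4.11), Plet1 55 and 0, Adora2a 52 and 2, Gm36079 62 and 3 and Siglecl1 75 and 6. In immature neutrophil-like cells Mx1 had 57 and 8 (-3.39), Hormad1 61 and 2, Gm41555 60 and 2, Gm42884 50 and 6 and Gm12250 88 and 14, while Gm26316 had 0 and 55. The genes with the highest ratios in these classes were otherwise haemoglobin genes and the red-cell genes Ahsp and Slc4a1, at 18 and 137 and at 10 and 43 UMIs. For Cartpt, Plet1 and Gm26316, with 0 UMIs in 1 library, a ratio is only a bound. Over all cells Xist stood at 235 and 205 CPM and the Y-linked Ddx3y at 6.67 and 7.38, while Uty had 44 and 35 UMIs, Kdm5d 1 and 0, Tsix 85 and 137, and Eif2s3y none in either library.

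Explanations by free RNA, scaling and neutrophil subtypes were weighed for the interferon pattern. With free RNA subtracted, the middle of the class medians stayed at -1.68 (counting SD 0.0895). That middle is the value of NK-like cells, where the estimate of free RNA is void in library 2, so it decides nothing alone. The estimate is void where a few cells hold most haemoglobin, as in macrophage-like cells, where it reached 100% and 75.4%, and in library 2 in Schwann-like cells (69.9%), NK-like cells (42.4%) and the Spp1 cluster (38.7%). In monocyte-like cells, where it took only 3.49% and 3.045% of UMIs, the list stayed at -3.03. The step took 3.64% and 3.709% in pro- or pre-B-like and 5.294% and 6.163% in T-cell-like cells, and the list stayed at -2.42 and -1.59. In these classes the 5% of cells with most haemoglobin UMIs held at most 46.3% of them. Their values argue against free RNA as the whole cause there. Endothelial-like cells, with at most 46.1% so held, hardly differed, at -0.04 before and 0.09 after. The step moved the list from -2.18 to -1.12 in immature neutrophil-like, from -1.90 to -1.35 in megakaryocyte-like and from -0.09 to 1.27 in osteoblast-like cells. But there such cells held 78.7%, 68.6% and 80.9% of the haemoglobin UMIs of library 1, so the estimate is void there too. Whether free RNA is a part of the cause in some classes stays open. Centring each class on the median of all genes left -1.88 (SD 0.121), so scaling is no sufficient cause. Within the mature neutrophil clusters the list stood at -1.04 (SD 0.105) and -1.48 (SD 0.0435), where the bound of -1 written before was not passed by 2 SD in the first. Their unequal weights were set aside as the cause by a criterion added later, since both values lie below -0.5 by more than 2 SD and 14 other classes also lay below the random range, so a real difference between the pools, in the animals or in their handling, may remain and was not tested.

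Haemoglobin genes were higher in library 2 in 22 of 22 classes, with a middle value of 2.90. Outside cells they stood at 6962 CPM in library 1 and 43740 in library 2, and with free RNA subtracted the list was higher in only 1 class, as that step requires because haemoglobin sets the amount removed. Free RNA therefore stays open as the source of the shift between the libraries. Within library 2 the haemoglobin share also differed between classes that should lack it. Free RNA alone adds a like number of UMIs to each cell, so shares can differ with depth, and a bound of 5 times on shares is too low across classes of unlike depth. But the highest share was 24.8 times the lowest, between macrophage-like cells with 3.30% of UMIs and monocyte-like cells with 0.133%, whose median depths were alike at 5795 and 6085.5 UMIs, so free RNA alone does not account for this inequality. The median count of haemoglobin UMIs per cell was 8 and 7 in these classes. A few cells holding red-cell RNA may account for the high shares. In the 5 classes with the highest share, the 5% of cells with most haemoglobin UMIs held at least 75.2% of them, and 94.6% in Schwann-like and 93.4% in macrophage-like cells, while in monocyte-like cells they held 27.7%. Whether these cells are doublets, cells that engulfed red cells or barcodes shared with red cells was not tested, and the 63 Schwann-like cells of library 2 also held progenitor granule genes.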
